A study of Mus musculus with 22 samples.

How the data were processed

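MicroRNAs (miRNAs) were measured on 22 Agilent mouse miRNA arrays in 3 kinds of sample (tissue of the small intestine, blood serum, and feces) from male mice aged 8 weeks that received X-rays of 10 Gy, delivered at 1.0 Gy per minute, or 0 Gy. Each array was hybridised with Cy3-labelled RNA of 1 sample. The groups held 4 arrays at each dose for intestine and for feces, and 2 arrays at 0 Gy and 4 at 10 Gy for serum. The labels do not give the time between irradiation and collection. Nor do they say whether the samples of a group came from separate animals, so the p-values measure the spread between these samples, part of which may be technical. Per the file headers, each sample type was hybridised on 1 of 3 slides, so sample type and slide cannot be told apart. Within each slide the 0 Gy samples lay in columns 1 and 2 and the 10 Gy samples in columns 3 and 4, so dose and column cannot be told apart either, while each of the 2 rows of a slide held both doses. All arrays were scanned on 1 day.

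The deposited files hold the scanner output of each array. Per the file headers and the submitters' processing notes, the authors made these values with Agilent Feature Extraction 11.5, whose miRNA protocol subtracts a background with spatial detrending for each spot. The deposited intensity used here, the processed signal, is on a linear scale and was not normalized between arrays, per the file headers. The deposited median intensity of each spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or outlying, were also used. Each array had 58594 spots, of which 56430 belonged to 4415 probes of 1881 mouse miRNAs. Of these miRNAs, 4 had 1 probe, 1493 had 2, 111 had 3 and 273 had 4. The array design names the mm9 build, which is not used here, so no coordinates are given. A GRCm38.p6 annotation served only to look up which miRNA genes lie within the gene Sfmbt2. The authors' series table was set against the scanner values. In every column all 58594 values lay within 1% of the processed signal, so it is linear and not centred, and its column medians ranged from -1.55 to 2.1.

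For each array the processed signal was averaged over the spots of a probe that were not outlying, and then summed over the probes of a miRNA. A miRNA was detected on an array when at least 1 of its probes had 50% or more of its spots well above background. Values were divided by the array's 75th percentile over the miRNAs detected on all arrays of the sample type (268 in intestine, 121 in serum, 326 in feces), raised to a floor and taken to log2. The floor was the median over the arrays of the lowest scaled value of a detected miRNA. For comparisons between sample types the percentile was taken over the 81 miRNAs detected on all 22 arrays. The number of arrays limits the precision of every value.

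Doses were compared within each sample type with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over the miRNAs detected on at least as many arrays as the smaller group held. P-values were adjusted by the Benjamini-Hochberg method, and a miRNA passed below 0.05. Differences between sample types in the dose effect, and levels in unirradiated feces or serum against intestine, were tested in 1 limma fit of all 6 groups. A change is the log2 value at 10 Gy minus that at 0 Gy, with the standard error (SE) of the fit. Where a miRNA was not detected on any array of a group, the fold is written as at least N-fold. It was taken for each probe detected on every array of the bright group, as the mean of that group against the dim group's mean of, per array, the higher of the lowest signal of a detected probe and the probe's own. The lowest value over the probes is given, or the fitted fold where that was smaller, and none where it was under 1. It can lie far below the change, which sums the probes. Effects in pairs of sample types were correlated across miRNAs, with p-values from 100 regroupings of the dose labels. Numbers of detected miRNAs were compared by exact two-sided permutation tests, and overlaps of calls by one-sided Fisher's exact tests.

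The tests, most of the processing alternatives, 12 lists of miRNAs and a rule for the miRNAs to be named were fixed before the data were examined. For each dose comparison the rule takes up to 12 rises and 12 falls that passed without overlap between the arrays of both doses, in order of the size of the change, up to 4 passing members of each list, and every miRNA that passed in at least 2 sample types. Between sample types it takes the 8 highest, the 8 lowest and up to 4 list members. The lists were p53-responsive miRNAs, intestinal epithelium, smooth muscle and mesenchyme, leukocytes, erythrocytes, liver, endothelium, neurons, the miR-17/92 and miR-106b/25 clusters, the let-7 family, the miR-29 and miR-30 families, and radiation and DNA damage response. miR-192-5p, miR-194-5p, miR-215-5p and miR-200c-3p are in both the p53 and the epithelium list. The list of the miR-17/92 and miR-106b/25 clusters also holds miR-20b-5p and miR-106a-5p, whose genes lie in another, related cluster. The members miR-106a-5p, miR-486b-5p and miR-885-5p are not among the names on the array. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated from the data by limma.

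The alternatives were the 75th percentile over all miRNAs, quantile normalization, no scaling, normexp background correction with an offset of 50, other filters on dim miRNAs, the brightest probe, the scanner software's total gene signal, the authors' series table, a lower floor, other variance models, array weights, the replicate number as a block, 1 fit of all groups, and leaving out each array. The files hold no mean spot signal, so normexp was run on the median spot signal. The row of the slide as a block, tests within each row, fits of only the arrays compared, and list tests under 2 further scalings were added after the data were seen. The comparison step was tested on simulated data with 40 changed miRNAs in 20 simulations. At a log2 change of 1 it recovered 91.3% of them in intestine (335 miRNAs), 51.8% in serum (193 miRNAs) and 5.63% in feces (491 miRNAs). At a log2 change of 2 it recovered 99.8%, 96.4% and 86.6%, and false calls made up 4.41% to 6.25% of calls. The simulated errors were normal, independent between miRNAs and added after scaling, flooring and filtering. The simulation therefore does not show how often calls are false on real arrays, where errors can be shared across miRNAs. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.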

Results

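The study asked how miRNAs in the small intestine, in serum and in feces differ between mice given a high dose of X-rays and unirradiated mice. Feces gave the most detected miRNAs per array, 526.5 ± 130 at 0 Gy and 469 ± 23.3 at 10 Gy (mean ± SD, n = 4 each), and serum the fewest, 197 ± 31.1 (n = 2) and 154.5 ± 23.3 (n = 4). These counts did not differ beyond the spread in feces (exact two-sided permutation p = 0.429) or serum (exact p = 0.2, where 0.0667 is the smallest possible). In intestine the number of detected miRNAs rose from 294.5 ± 6.66 to 365.75 ± 27.4 (n = 4 each, exact two-sided permutation p = 0.0286, the smallest possible). The summed signal of detected miRNAs in intestine was 321483 at 0 Gy and 401924 at 10 Gy (exact permutation p = 0.0286). Arrays of a group correlated with each other at r between 0.897 and 0.993 across miRNAs, and no spot was saturated. Among feces arrays, 0 Gy replicate 3 stood apart, with 675 detected miRNAs and the lowest score (-22.6) on the first principal component, which held 48.7% of the variance.

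In irradiated small intestine, miR-34a-5p, a direct transcriptional target of p53, was 10.1-fold higher, a log2 change of 3.33 ± 0.19 (SE, n = 4 against 4, limma adjusted p = 7.7e-08). Its relative miR-34b-5p was detected on all 4 arrays at 10 Gy and on 0 of 4 at 0 Gy, at least 1.08-fold higher (1.19 ± 0.17, adjusted p = 0.00028). miR-150-5p, which is abundant in mature lymphocytes, was lower (-2.32 ± 0.43, adjusted p = 0.0014) and was detected on 1 of 4 arrays at 10 Gy. miR-223-3p, abundant in granulocytes, was 2.30-fold higher (1.20 ± 0.19, adjusted p = 0.00047). Of 13 tested epithelial miRNAs 7 fell, and 8 fell of 10 in the list of the miR-17/92 and miR-106b/25 clusters, which are highly expressed in proliferating cells (camera adjusted p = 0.00026 each, adjusted p = 0.91 each with an estimated correlation).

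By limma, 140 of the 335 tested miRNAs changed in intestine, 87 higher and 53 lower, on arrays that also detected more miRNAs at 10 Gy (365.75 against 294.5). Of the 140, 121 did not overlap between the doses. Of all 335, 132 (39.4%) did not overlap, where chance gives 2 of the 70 orderings of 4 and 4 arrays. Rises beside miR-34a-5p were at least 1.34-fold for miR-877-5p (2.67 ± 0.20, adjusted p = 1.5e-06, and 0.90 to 1.06 for its detected probes) and at least 1.58-fold for miR-3091-5p (2.48 ± 0.19, probes 1.14 to 1.75). miR-721, miR-714, miR-680, miR-8109, miR-3154, miR-3102-5p, miR-7118-5p and miR-139-3p also rose, by log2 changes between 1.49 and 2.34. Their detected probes gave changes from 0.57 (miR-8109) to 1.82 (miR-721). Those of miR-680 (0.85 to 1.01), miR-3154 (1.12 to 1.24) and miR-139-3p (1.21) all lay below 1.49. miR-483-5p, encoded within the insulin-like growth factor gene Igf2, was detected on every array of both doses and was 3.49-fold higher (1.80 ± 0.24, adjusted p = 1e-04). Of the 140, 24 were not detected on any 0 Gy array. Falls beside miR-150-5p were those of miR-7687-5p, at least 1.95-fold (-1.84 ± 0.21, adjusted p = 4.3e-05, probes -1.06 and -0.98), miR-7002-5p (-1.73 ± 0.34) and miR-194-1-3p (-1.65 ± 0.32), an arm of an epithelial miRNA hairpin. miR-677-3p, miR-7005-5p, miR-130b-3p, miR-344i, miR-6931-5p and miR-194-2-3p also fell, by log2 changes from -1.42 to -1.14. Among called miRNAs with more than 1 detected probe, the probes had opposite signs in 0 of 98, and in 0 of 8 in serum and 1 of 26 in feces (miR-710, -0.73 to 1.14). With normexp background correction, whose offset of 50 compresses dim signals, 91 miRNAs passed, 25 higher and 66 lower. miR-877-5p, miR-714, miR-680, miR-3154, miR-139-3p, miR-34b-5p, miR-486a-5p, miR-218-5p, miR-210-3p and miR-7088-5p then had changes between -0.15 and -0.0032. miR-3091-5p (0.12), miR-721 (0.15), miR-8109 (0.0323), miR-483-5p (0.25), miR-214-3p (0.28), miR-17-5p (-0.19) and miR-494-3p (-1.31) kept their direction but no longer passed.

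**Figure D1:**
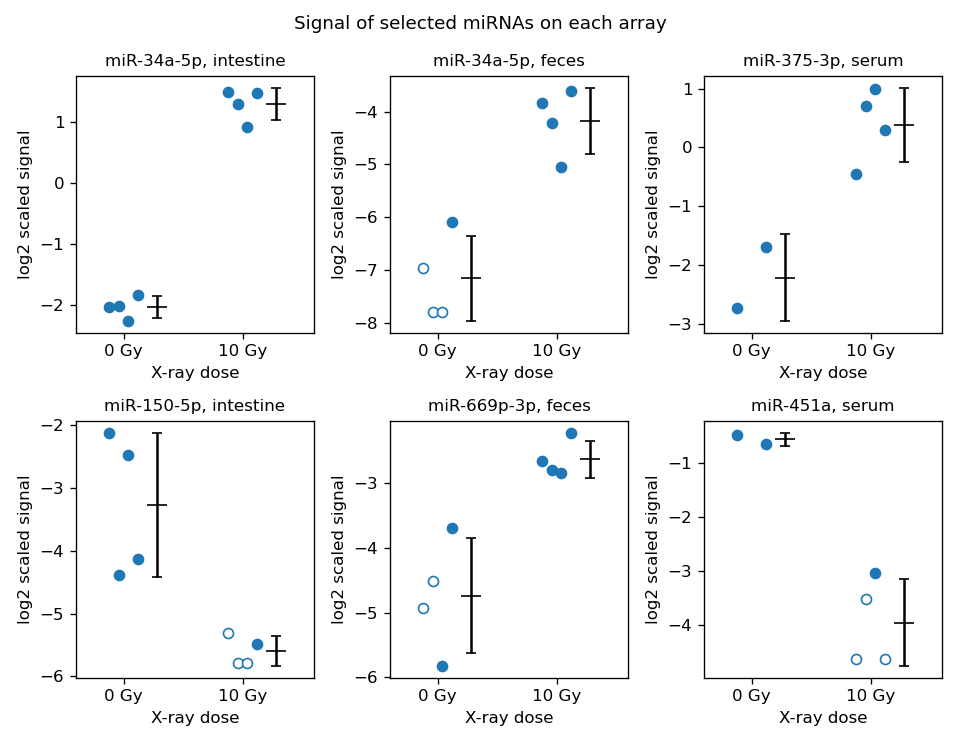
Scaled signal (log2) of 6 miRNA and sample type pairs against X-ray dose in Gy, where each point is an array, filled if the miRNA was detected there and open if not, and the bar and whiskers are the mean ± SD. miR-34a-5p lay higher at 10 Gy in intestine (change 3.33) and feces (2.98), as did miR-375-3p in serum (2.61) and miR-669p-3p in feces (2.11), while miR-150-5p lay lower in intestine (-2.32) and miR-451a in serum (-3.41).

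The 7 of 13 epithelial miRNAs that fell in intestine became 10 when adjusted over the list alone, and 0 rose. miR-378a-3p changed by -1.02 ± 0.20 (adjusted p = 0.0019), miR-200c-3p and miR-200b-3p, which repress the transcription factors Zeb1 and Zeb2, by -0.79 ± 0.20 each (adjusted p = 0.0084), miR-31-5p by -0.71 ± 0.21 (adjusted p = 0.018) and the enterocyte miRNA miR-192-5p by -0.61 ± 0.21 (adjusted p = 0.033). The fall of miR-192-5p passed in 13 of 25 alternatives, and did not pass without scaling (-0.14). With quantile normalization its change was 0, a value that this method gives any miRNA of the same rank on every array. That 0 may be by construction and cannot show that the fall was gone. miR-375-3p (-0.07), miR-203-3p (-0.08) and miR-802-5p (0.01) of the same list did not pass. The 8 of 10 members of the miR-17/92 and miR-106b/25 list that fell became 9 when adjusted over the list alone. Among them were miR-20b-5p, whose gene lies in another, related cluster (-0.74 ± 0.19, adjusted p = 0.0088), miR-93-5p (-0.70 ± 0.18), miR-17-5p (-0.68 ± 0.18) and miR-25-3p (-0.65 ± 0.18). miR-18a-5p (-0.12) and miR-19b-3p (-0.43) did not pass. The scaling set the level of all changes. The median change of all tested miRNAs was 0.16, and 0.01 with quantile normalization, -0.35 with the percentile over all miRNAs and 0.62 without scaling, where 55 and 66, 21 and 86, and 186 and 13 miRNAs were higher and lower. Relative to these medians the epithelial median was -0.79, -0.59, -0.79 and -0.78 and the cluster median -0.75, -0.64, -0.72 and -0.74, in the same order. The scalings other than quantile normalization differ by 1 constant per array. Their values can differ here only through the floor, so the quantile value is the only separate check. Without scaling the calls of lower members were 1 of 13 and 0 of 10, with 1 cluster member called higher.

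Among 12 tested miRNAs of smooth muscle and mesenchyme in intestine 4 rose, 4 also when adjusted over the list alone, namely miR-214-3p (1.03 ± 0.18, adjusted p = 0.0011), miR-199a-5p (0.82 ± 0.18), miR-199a-3p (0.80 ± 0.17) and miR-125b-5p (0.49 ± 0.17, adjusted p = 0.035). The list as a whole did not pass (limma adjusted p = 0.13), but did without scaling (adjusted p = 0.0163, and 0.016 to 0.91 over the alternatives, the highest with an estimated correlation). Its median relative to that of all miRNAs was 0.21 with quantile normalization and 0.16 with the other scalings, which can differ here only through the floor. The calls did differ, with 0 members called under the percentile over all miRNAs and 12 without scaling. Of the 10 tested leukocyte miRNAs, 2 rose and 3 fell, also over the list alone (camera adjusted p = 0.53). miR-142a-3p (-1.04 ± 0.22, adjusted p = 0.0034) and miR-142a-5p (2.00-fold lower, adjusted p = 0.02), expressed throughout blood cells, fell with miR-150-5p, while miR-223-3p rose together with miR-146b-5p (0.82 ± 0.16), which was named after its values were seen. In the p53 list 3 of 13 rose and 2 fell (3 and 6 over the list alone, camera adjusted p = 0.55). The riser beside the miR-34 pair, miR-23a-3p (0.54 ± 0.17), was named after its values were seen, and the members that fell were miR-200c-3p and miR-192-5p, which the epithelium list also holds. Of 18 tested radiation-response miRNAs 5 rose and 2 fell, also over the list alone (camera adjusted p = 0.75), among them miR-210-3p, induced by hypoxia (0.79 ± 0.18), miR-24-3p (0.58 ± 0.17), miR-27a-3p (0.57 ± 0.18) and miR-21a-5p (0.55 ± 0.17). The neuronal list had 1 riser of 3, miR-218-5p (0.74 ± 0.18, camera adjusted p = 0.53). No member of let-7 (9 tested, adjusted p = 0.53) or of miR-29 and miR-30 (8 tested, adjusted p = 0.75, median 0.03 against a camera direction of down) passed. Of the remaining cell types too few members were tested for camera. miR-486a-5p of erythrocytes rose (0.66 ± 0.17, adjusted p = 0.011), but its only detected probe changed by 0.29. miR-451a of erythrocytes (0.21 ± 0.26) and miR-126a-3p of endothelium (0.44 ± 0.18) did not pass, and 0 liver miRNAs were tested in any sample type. Leaving out single arrays ended some of these calls. miR-125b-5p (0.41 to 0.52) passed only when the array left out was 10 Gy replicate 3 (0.58). miR-192-5p lost its call without 0 Gy replicate 2, 3 or 4 (-0.56, -0.65, -0.55) or 10 Gy replicate 2 or 3 (-0.58, -0.44), and miR-142a-5p without 0 Gy replicate 3 (-0.81) or 10 Gy replicate 1 or 3 (-0.88, -0.95).

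**Figure D2:**
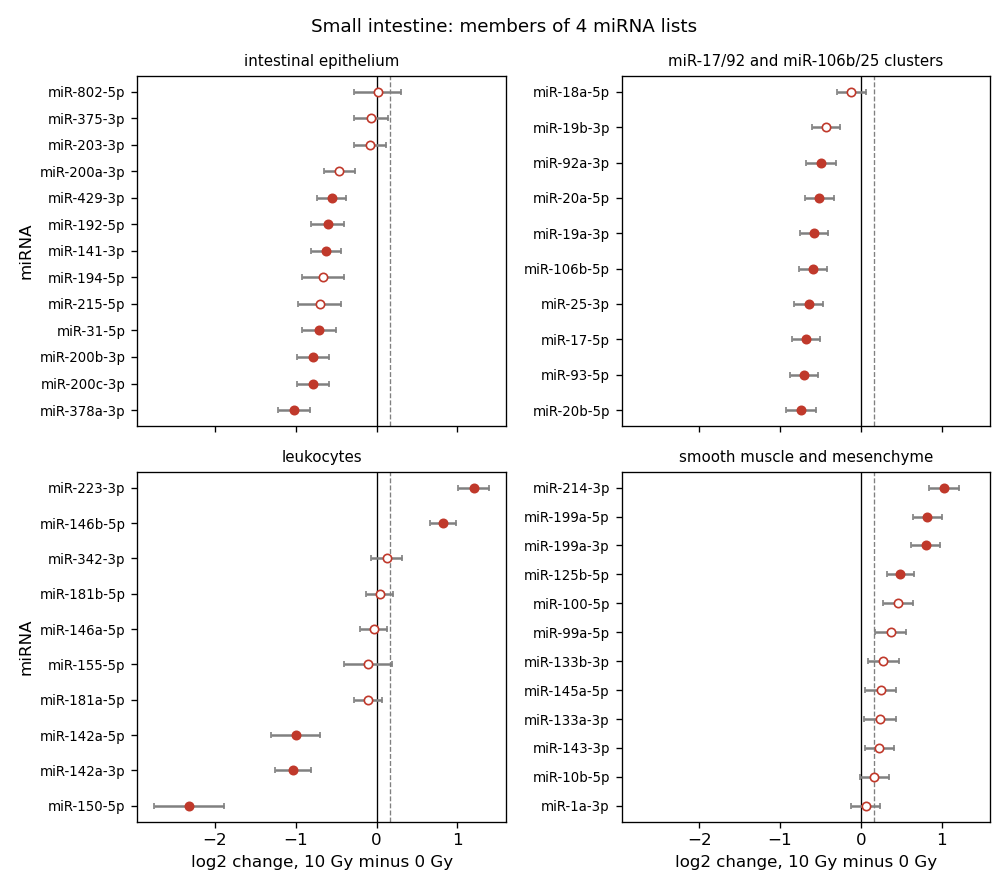
Change in intestine (log2, 10 Gy against 0 Gy, ± SE, n = 4 each) of the tested members of 4 lists, filled where the limma adjusted p passed, with a dashed line at the median of all tested miRNAs (0.16). The medians of the epithelial and of the miR-17/92 and miR-106b/25 members lay below that line (-0.63 and -0.59), while leukocyte miRNAs ranged from miR-150-5p (-2.32) to miR-223-3p (1.20), and without scaling the medians of the lower lists were -0.16 and -0.12.

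In irradiated serum, miR-375-3p, an islet and epithelial miRNA, was 6.08-fold higher (2.61 ± 0.47, n = 2 against 4, limma adjusted p = 0.028), and miR-574-3p, near the floor and detected on 1 of 2 arrays at 0 Gy, was higher too (2.52 ± 0.39, adjusted p = 0.018, and 0.58 to 1.85 for its detected probes). miR-451a, an abundant miRNA of red blood cells, was lower (-3.41 ± 0.49, adjusted p = 0.015), detected on 1 of 4 arrays at 10 Gy and otherwise near the floor. Its change ran from -4.04 without scaling to -0.89 with normexp. miR-486a-5p, also abundant in red blood cells, was 2.76-fold lower (-1.46 ± 0.25, adjusted p = 0.024). miR-34a-5p was detected on too few serum arrays to be tested.

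By limma, 9 of 193 tested serum miRNAs changed, 2 higher and 7 lower. All 9 did not overlap between the doses, as did 58 (30.1%) of all tested miRNAs, where chance gives 2 of the 15 orderings of 2 and 4 arrays. The other falls were miR-344i (-2.58 ± 0.28, adjusted p = 0.0069), miR-7031-5p, at least 1.25-fold (-1.74 ± 0.22, probes -0.79 and -0.69), miR-222-3p (-1.67 ± 0.35), miR-30d-5p (-1.04 ± 0.22) and miR-1198-5p, not detected at 10 Gy (-0.96 ± 0.18). Quantile normalization gave 3 higher and 6 lower, and no scaling 0 and 3. The median change of all tested miRNAs was -0.11, -0.05 with quantile normalization, -0.32 with the percentile over all miRNAs and -0.84 without scaling. Without 0 Gy replicate 1 or 2 the number of changed miRNAs was 5 and 4, and without 10 Gy replicates 1 to 4 it was 16, 6, 14 and 3. Of the 9, miR-344i and miR-7031-5p passed whichever array was left out, but with normexp miR-344i had a change of -0.36, miR-7031-5p one of 0.00149, miR-1198-5p one of 0.076 and miR-222-3p one of -0.0129, and none of the 4 passed. Without either 0 Gy array miR-375-3p (2.07, 3.13), miR-574-3p (2.26, 2.75), miR-451a (-3.31, -3.47), miR-486a-5p (-1.60, -1.34), miR-222-3p (-1.85, -1.48) and miR-30d-5p (-1.05, -1.04) no longer passed. The same was true of miR-375-3p without 10 Gy replicate 2 (2.46) or 4 (2.65), and of miR-574-3p (2.53) and miR-486a-5p (-1.37) without 10 Gy replicate 4. It was also true of miR-1198-5p without 10 Gy replicate 2 (-1.02) or 4 (-1.05), and of miR-222-3p (-1.64, -1.80, -1.43) and miR-30d-5p (-1.01, -1.10, -0.95) without 10 Gy replicate 1, 2 or 4.

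No list passed in serum. The miR-29 and miR-30 families had 1 lower member of 4, miR-30d-5p, also over the list alone (camera adjusted p = 0.10, and 0.58 with an estimated correlation). The p53 list (0 of 3, also over the list alone, adjusted p = 0.39) and smooth muscle and mesenchyme (0 of 5, also over the list alone, adjusted p = 0.40) had no member that passed. In the radiation list 0 of 3 passed, and 1 when adjusted over the list alone, miR-24-3p (2.19 ± 0.52, adjusted p = 0.062 over all tested), while the list's median was -0.63 and its camera direction up (adjusted p = 0.90). Both tested erythrocyte miRNAs fell, miR-451a and miR-486a-5p. For the other lists few members were tested. These were miR-375-3p and miR-378a-3p (0.67 ± 0.29) of epithelium, miR-25-3p (-1.63 ± 0.36, adjusted p = 0.051) and miR-92a-3p (-1.29 ± 0.58) of the miR-17/92 and miR-106b/25 clusters, miR-342-3p (0.57) of leukocytes and miR-138-5p (0.61) of neurons, and 0 members of let-7 and endothelium.

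In feces of irradiated mice miR-34a-5p was higher (2.98 ± 0.46, n = 4 against 4, limma adjusted p = 0.013) and was detected on all 4 arrays at 10 Gy and on 1 of 4 at 0 Gy. Of 11 tested members of the miR-466, miR-467 and miR-669 family, many of whose genes lie in an intron of Sfmbt2, 8 rose. The family was singled out after its values were seen, and it had 0 calls without 0 Gy replicate 1 or any 1 of the 10 Gy arrays, with medians from 1.73 to 2.19. Among the 8 were miR-466g (2.48 ± 0.60, adjusted p = 0.045, and 1.57 to 1.66 for its detected probes), miR-466q (2.46 ± 0.49, adjusted p = 0.028), miR-669c-3p (2.15 ± 0.40) and miR-669p-3p (2.11 ± 0.42). miR-574-3p, detected on 1 of 4 arrays at 0 Gy, rose by 1.93 ± 0.47 (adjusted p = 0.046). miR-7083-5p and miR-7679-5p, detected on all 4 arrays at 0 Gy and on none at 10 Gy, fell (-4.15 ± 0.61, at least 6.95-fold, adjusted p = 0.012, and -3.41 ± 0.26, adjusted p = 0.00018). No single probe of miR-7679-5p was detected on 4 arrays, so its detection came from different probes and no fold bound could be given.

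By limma, 37 of 491 tested fecal miRNAs changed, 17 higher and 20 lower. Over the alternatives that kept all feces arrays the number ran from 3 (1 and 2, over miRNAs detected on every array) to 171 (105 and 66, with array weights) and 192 (110 and 82, in 1 fit of all groups). Within slide rows 1 and 2, each with fewer arrays, it was 28 and 0. All 37 did not overlap between the doses, as did 143 (29.1%) of all tested miRNAs, where chance gives 2 of the 70 orderings. The named family members also included miR-466f-3p (2.14 ± 0.42), miR-466i-3p (2.13 ± 0.45), miR-467f (1.83 ± 0.42) and miR-466h-3p (1.74 ± 0.38). The median change of the family was 2.11, and 1.96, 2.08 and 1.27 with quantile normalization, the percentile over all miRNAs and no scaling. Other rises were miR-690 (1.86 ± 0.47), miR-7242-5p (1.67 ± 0.36), miR-494-3p (1.41 ± 0.34) and miR-8110 (1.12 ± 0.28). Of the falls, miR-671-3p (-2.01 ± 0.26, adjusted p = 0.0077), miR-3073a-5p (-2.30 ± 0.46), miR-3091-5p (-2.01 ± 0.42) and miR-7039-5p (-1.93 ± 0.41) were not detected at 10 Gy and were at least 1.26, 2.40, 1.92 and 2.16-fold lower. miR-6989-5p, miR-3061-5p, miR-6901-5p, miR-187-5p, miR-1945, miR-183-3p and miR-7088-5p fell too, by log2 changes from -2.37 to -1.45. Without scaling 1 miRNA was higher and 26 lower, and the median change of all tested was -0.49 in place of 0.15. The number of changed miRNAs was 4, 34, 20 and 137 without 0 Gy replicate 1, 2, 3 or 4, and 19, 6, 6 and 4 without 10 Gy replicate 1, 2, 3 or 4. miR-671-3p passed whichever array was left out, as did miR-7679-5p, of which no single probe was detected on 4 arrays. miR-34a-5p lost its call without 10 Gy replicate 2 (3.27) and miR-7083-5p without 10 Gy replicate 4 (-3.91). With normexp 1 miRNA was higher and 2 lower, and of the named ones only miR-494-3p, miR-7088-5p and miR-1945 passed. miR-34a-5p then had a change of 0.47 and miR-7679-5p one of -0.11, while miR-671-3p (0.32), miR-7039-5p (0.0236) and miR-183-3p (0.16) turned direction.

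No list passed in feces (camera adjusted p = 0.22 for p53, epithelium, miR-17/92 and miR-106b/25, miR-29 and miR-30, and radiation, 0.27 for let-7, and 0.67 for each with an estimated correlation). Without scaling 5 of these 6 lists passed as up (adjusted p between 0.0200 and 0.0228, against 0.17 to 0.21 with the other scalings), and let-7 did not (adjusted p = 0.0902). The p53 and radiation lists each had 1 riser, miR-34a-5p, of 10 and 11 tested members, also when adjusted over the list alone. None passed of 11 epithelial, 6 miR-17/92 and miR-106b/25, 7 let-7 and 8 miR-29 and miR-30 members, over all or over the list alone. In smooth muscle and mesenchyme miR-133a-3p (0.70 ± 0.23) and miR-133b-3p (0.77 ± 0.24) were tested, in leukocytes miR-181a-5p (-1.65 ± 0.51, adjusted p = 0.075) and miR-181b-5p (-0.68), and in erythrocytes miR-486a-5p (0.29 ± 0.27), and none passed. Of endothelium and neurons 0 members were tested.

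The dose effect was compared between sample types in the limma fit of all groups, which shares 1 estimate of the spread over the sample types. In that fit the dose calls went from 37 to 192 in feces, from 9 to 21 in serum and from 140 to 115 in intestine. The errors and adjusted p-values of differences that involve feces or serum may therefore be too small. The changes of miR-34a-5p in feces and intestine differed by -0.35 ± 0.46, within the error (n = 4 in each of 4 groups, adjusted p = 0.56). miR-3091-5p rose in intestine and fell in feces (difference -4.49 ± 0.45, adjusted p = 2.1e-07), although with normexp neither change passed (0.12 and -0.18), and that in feces passed in 16 of 24 alternatives. miR-7088-5p moved in the same directions, with a difference of -2.39 ± 0.49 (adjusted p = 0.0018). miR-494-3p fell in intestine (-1.40 ± 0.44) and rose in feces (1.41 ± 0.34), a difference of 2.81 ± 0.61 (adjusted p = 0.0019). In intestine miR-7088-5p (0.94 ± 0.32) lost its call without 0 Gy replicate 2, 3 or 4 (0.93, 0.97, 0.71) or 10 Gy replicate 2 or 3 (0.69, 0.87), and miR-494-3p without 0 Gy replicate 3 (-1.33) or 10 Gy replicate 1 (-1.17). The changes of miR-375-3p and miR-574-3p were higher in serum than in intestine (2.67 ± 0.77 and 2.10 ± 0.61, n = 2 and 4 serum arrays, adjusted p = 0.013 each), and that of miR-451a was lower (-3.62 ± 0.50, adjusted p = 4.7e-05). The effect on miR-574-3p did not differ between feces and serum by more than its error (-0.60 ± 0.60, adjusted p = 0.52).

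In all, 59 of 219 miRNAs tested in both feces and intestine differed in the effect, 23 with a higher and 36 with a lower value in feces, and 54 and 15 with the percentile over all miRNAs. Between serum and intestine 31 of 144 differed, 4 higher and 27 lower, or 4 and 12 with that percentile, and between feces and serum 11 of 164, 7 higher and 4 lower in feces, or 7 and 2. miRNAs that passed in both feces and intestine in the same direction were miR-34a-5p and miR-8110, both higher, although miR-8110 passed in feces in only 9 of 25 alternatives (adjusted p from 0.00058 to 0.87). Independent lists would share 3.26 such miRNAs (one-sided Fisher's exact p = 0.883). miR-1198-5p and miR-344i (-1.21 ± 0.24 in intestine) fell in both serum and intestine, where independent lists would share 0.521 (one-sided Fisher's exact p = 0.0845). miR-486a-5p fell in serum and rose in intestine, where its only detected probe changed by 0.29. miR-574-3p rose in both feces and serum (0.0732 by independent lists, exact p = 0.072). Across miRNAs, which are not independent replicates, the effects in feces and intestine correlated at Pearson r = -0.107 and Spearman rho = -0.169 (219 miRNAs, permutation p = 0.614 and 0.525), and those in serum and intestine at r = 0.152 and rho = 0.13 (144 miRNAs, permutation p = 0.485 and 0.455). Adjusted over the 2 correlations, the p-values were 0.614 for r and 0.525 for rho.

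Without irradiation, feces held far lower relative levels of the miRNAs of the intestinal wall than the small intestine. This was not particular to the wall, since the let-7 family had a median of -7.90 and the epithelium list one of -6.91. miR-215-5p, an enterocyte miRNA, was lower in feces (-9.02 ± 0.49, n = 4 against 4, and -9.29 to -5.71 over the alternatives, the smallest without scaling), and miR-194-5p (-8.15 ± 0.55), miR-200c-3p (-8.01 ± 0.45), miR-3968 (-8.66 ± 0.23), let-7a-5p, let-7b-5p, let-7c-5p and let-7f-5p (-8.42 to -8.08) were lower as well. miR-143-3p of smooth muscle, miR-126a-3p of endothelium and miR-142a-3p of blood cells were not detected in feces and were at least 245, 184 and 119-fold lower. Higher in feces were miR-7088-5p (6.86 ± 0.24, and 6.71 to 10.22 over the alternatives) and miR-483-5p (6.68 ± 0.24, and 6.55 to 10.05), and miR-7052-5p, miR-762, miR-6370, miR-6942-5p, miR-1896 and miR-1945 were at least 25.5, 1.58, 18.1, 2.95, 9.26 and 7.67-fold higher.

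Of 492 miRNAs 406 differed between feces and intestine in limma, 176 higher and 230 lower in feces. The split was 241 and 200 with the percentile over all miRNAs, 257 and 189 with quantile normalization and 311 and 163 without scaling. Camera called all 8 testable lists lower in feces (limma adjusted p between 0.00033 and 0.0022, adjusted p = 0.19 for each with an estimated correlation). All tested members were lower in the p53 (12), epithelium (13), smooth muscle and mesenchyme (12), leukocyte (9), let-7 (9) and miR-29 and miR-30 (8) lists, 9 of 10 in miR-17/92 and miR-106b/25, and 18 of 19 with 1 higher in the radiation list. The counts were the same when adjusted over the list alone. In the lists too small for camera, miR-451a of erythrocytes was at least 20.7-fold lower, and of neurons miR-128-3p was at least 4.10-fold lower and miR-7a-5p was lower (-4.14), and miR-126a-3p was the only tested member of endothelium.

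In unirradiated serum miR-486a-5p was at least 227-fold higher than in intestine (9.26 ± 0.27, n = 2 against 4). miR-1897-5p (5.33, and 4.96 to 6.81 over the alternatives) and miR-3473f (4.08, and 3.85 to 5.66) were higher too, as were miR-8093, miR-3067-3p, miR-208a-5p, miR-205-5p and miR-5118 by at least 6.76, 5.83, 4.20, 4.39 and 2.46-fold. The epithelial miRNAs miR-194-5p, miR-215-5p, miR-192-5p, miR-200b-3p and miR-200c-3p were not detected in serum and were at least 550, 110, 298, 103 and 115-fold lower. So were miR-21a-5p, let-7c-5p, let-7a-5p, miR-143-3p, miR-126a-3p and miR-142a-3p, by at least 306, 100, 111, 59.1, 44.1 and 20.4-fold, while miR-125b-5p was detected and lower (-5.78 ± 0.25). Of 347 miRNAs 305 differed in limma, 100 higher and 205 lower, or 133 and 169 with quantile normalization. Camera called 6 lists lower, namely epithelium (13 of 13 members lower) and let-7 (9 of 9, limma adjusted p = 0.0050 each), p53 (11 of 12) and radiation (17 of 19 and 1 higher, adjusted p = 0.0088 each), smooth muscle and mesenchyme (10 of 12, adjusted p = 0.0108) and miR-17/92 and miR-106b/25 (10 of 10, adjusted p = 0.0152). With an estimated correlation the adjusted p was 0.41 for each. Leukocytes (8 of 9 lower, adjusted p = 0.0617) and miR-29 and miR-30 (6 of 8 lower and 1 higher, adjusted p = 0.319) did not pass as lists, and all counts were the same when adjusted over the list alone. All alternatives tried, 456 values for the named miRNAs in feces and 370 in serum, kept the direction and the side of the threshold, but not the size, and the bounds given hold for 1 scaling.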

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

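The test of fecal RNA as the only source of rises in intestine, the values over splits of the intestine arrays or with separate 0 Gy arrays, the values for the 20 most feces-enriched miRNAs and the values within slide rows were chosen after the results were seen.

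The dose effect differed between feces and intestine for 59 miRNAs in the limma fit of all groups. Its shared spread may make the errors for feces and serum too small. It was higher in feces for miR-466q (2.31), miR-669c-3p (1.87), miR-466f-3p (1.98), miR-466i-3p (1.92), miR-669p-3p (2.00), miR-467f (1.80), miR-466h-3p (1.64), miR-574-3p (1.51), miR-690 (2.31), miR-494-3p (2.81), miR-7002-5p (2.02), miR-6931-5p (1.81), miR-378a-3p (1.63) and miR-200c-3p (1.91). It was lower in feces for miR-3091-5p (-4.49), miR-877-5p (-3.93), miR-721 (-3.21), miR-7088-5p (-2.39), miR-483-5p (-2.36), miR-139-3p (-2.06), miR-7118-5p (-1.94), miR-8109 (-1.91), miR-3154 (-1.81), miR-3102-5p (-1.81), miR-680 (-1.58) and miR-714 (-1.39). Between serum and intestine 31 miRNAs differed, with higher values in serum for miR-375-3p (2.67), miR-6931-5p (2.20), miR-574-3p (2.10) and miR-378a-3p (1.69). Lower in serum were miR-451a (-3.62), miR-721 (-3.11), miR-877-5p (-2.95), miR-3091-5p (-2.64), miR-3154 (-2.32), miR-486a-5p (-2.13), miR-3102-5p (-1.85), miR-483-5p (-1.73), miR-714 (-1.51), miR-7118-5p (-1.50), miR-344i (-1.37), miR-8110 (-1.12) and miR-30d-5p (-0.92). Between feces and serum 11 differed, among them miR-486a-5p (1.75), miR-30d-5p (1.39) and miR-8110 (1.26), higher in feces, and miR-7039-5p (-2.07) and miR-3091-5p (-1.85), lower in feces.

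Of 119 groups of 4 arrays examined, 2 had an array whose gap to the others, as a share of the range, passed Dixon's critical value for 4 values, where chance gives about 1 in 20. These were 10 Gy intestine replicate 3 for miR-194-1-3p (0.884), without which the change was -1.35 and still passed, and 10 Gy intestine replicate 1 for miR-7005-5p (0.930), without which the change was -1.23 and no longer passed.

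For the 140 changed miRNAs in intestine the highest of the other splits of the arrays gave 0. Only 1 of 35 splits, the real one, was as large, which is the smallest share possible. The same held for feces, with 37 against 2 (1 of 35), and for unirradiated feces against intestine, with 406 against 2 (1 of 35). Chance is thus an unlikely source of these counts, but the real splits are also those of slide column or of slide. For the difference between feces and intestine 59 stood against 50 (1 of 100 regroupings). There a regrouping of the doses gave nearly as many calls, so the count alone says little about a dose effect. The 15 splits of the serum arrays are too few for a share under 0.05, and the real split gave 9 and the highest other 0.

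Among miRNAs numbered 500 or higher, a set noticed in the data, 44 of 152 rose and 14 fell in irradiated intestine, against 43 and 39 of 183 with lower numbers, a difference of medians of 0.19 (0.02 to 0.36, bootstrap interval over miRNAs). As large a difference arose in 16 of 35 splits of the arrays (up to 0.59), so chance may account for it. Fecal RNA in the tissue samples as the only source of these rises was examined by the share of it each would need. For 28 of the 44 the lower bound of that share exceeded 5.91%. That is the upper bound of the median share needed for the 20 most feces-enriched miRNAs (3.71%). The share for miR-3091-5p, at least 256%, adds nothing to this. That miRNA was not detected in irradiated feces or unirradiated intestine, so the value is a ratio of signals near the floor. How many of the 28 shares rest on such signals was not tested. The 44 were chosen for their rise, which raises the share. The 20 were chosen for their level in feces relative to intestine, which lowers it. The comparison therefore cannot decide whether fecal RNA was the only source. As 1 source among others fecal RNA cannot be told apart from chance, since among the 152 the change followed the level in feces relative to intestine (Spearman rho = 0.404, and 0.491 to 0.555 with separate 0 Gy arrays for change and level), but as strongly in 9 of 35 splits. Scaling that depends on intensity (difference 0.139 with quantile normalization, 0.01 to 0.27), signal near the floor (0.20 among miRNAs detected on every intestine array, -0.0047 to 0.32, and 0.0094 with normexp) and a dose effect in the tissue, which no test addressed, stay open, as does the column of the slide, while the difference within rows 1 and 2 was 0.19 and 0.23.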

How the results depend on the processing

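The slide-row fits, the fits of only the arrays compared and the list tests without scaling or with the percentile over all miRNAs were chosen after the results were seen. The named miRNAs in both comparisons between unirradiated sample types (456 values in feces and 370 in serum), the numbers of detected miRNAs in feces and intestine and miR-34a-5p in intestine (25 of 25 settings) kept direction and side of the threshold under all alternatives run, while in serum that number could not pass (smallest possible exact permutation p = 0.0667). The split of the differing miRNAs in unirradiated feces did not hold (176 higher and 230 lower, 311 and 163 without scaling), nor did the list calls in either comparison (adjusted p = 0.19 and 0.41 with an estimated correlation). Of 1134 values for named miRNAs in intestine 1005 did so and 117 no longer passed, of 655 in feces 401 and 251, and of 201 in serum 124 and 75. Normexp gave 3 changed miRNAs in feces (37 in the report), 91 in intestine (140), and differences of effect for 29 (59, feces and intestine) and 8 (31, serum and intestine). It turned miR-671-3p to 0.32, miR-7039-5p to 0.0236 and miR-183-3p to 0.16 in feces, and miR-7031-5p to 0.00149 and miR-1198-5p to 0.076 in serum. In intestine it turned miR-877-5p to -0.0327, miR-714 to -0.15, miR-680 to -0.0402, miR-3154 to -0.0032, miR-139-3p to -0.057, miR-34b-5p to -0.047, miR-486a-5p to -0.10, miR-218-5p to -0.12, miR-210-3p to -0.094 and miR-7088-5p to -0.0603. It turned the correlations across miRNAs to r = 0.00399 (feces and intestine) and -0.0929 (serum and intestine). Its offset of 50 shrinks dim signals by construction, which limits what low signal over background can show. Other scalings turned miR-125b-5p in intestine to -0.0261 (percentile over all miRNAs) and miR-192-5p to 3.18e-15, in effect 0 (quantile). Quantile normalization gives any miRNA of the same rank on every array a change of 0, so that value may be by construction. Other scalings also gave 16 differences between serum and intestine (percentile over all miRNAs) and 3 changed serum miRNAs (no scaling). Without a filter 13 miRNAs changed in feces and 3 in serum, and over those detected on every array, fewer miRNAs by construction, 3 and 2. Array weights gave 171 in feces and 31 differences between feces and serum, and 1 fit of all 6 groups 192 in feces and 21 in serum. Within slide rows 1 and 2, with fewer arrays by construction, 28 and 0 changed in feces, 0 and 0 in serum (22 at an unadjusted limma p under 0.05 in each) and 50 and 56 in intestine, and in feces row 2 held 100 at an unadjusted p under 0.05. With the row as a block 34, 7 and 133 changed. With the replicate number as a block 39 changed in feces, 134 in intestine and 0 in serum (26 at an unadjusted limma p under 0.05). In serum replicates 3 and 4 had no 0 Gy array. By construction that fit therefore rests on replicates 1 and 2 alone and has little power. Same-numbered arrays deviated in both directions in feces (correlations -0.43 to 0.40) and intestine (-0.56 to 0.44), and the 2 positive values in serum (0.28 and 0.44) are too few to tell, so the numbers were not taken to pair samples. Leaving out each array gave 4 to 137 changed miRNAs in feces, 3 to 16 in serum, where a lone 0 Gy array is assumed to vary like the others, and 94 to 148 in intestine. With an estimated correlation 0 lists passed in the dose comparisons, and without scaling 8 (5 in feces and 3 in intestine), against 2. Except where construction is named, the cause was not tested. The slide as a block was not run, because each sample type was on 1 slide.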

Other observations

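The test of less RNA on the irradiated serum arrays, and the family values with arrays left out or within slide rows, were chosen after the results were seen.

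In irradiated serum miR-451a (-3.41 ± 0.49) and miR-486a-5p (-1.46 ± 0.25), both abundant in red blood cells, fell (limma adjusted p = 0.015 and 0.024, n = 2 against 4). Whether less RNA on the irradiated serum arrays, as a shift common to all miRNAs, was the whole cause could not be decided. Scaling moved the median change of all tested miRNAs from -0.84 to -0.11 and left the less lowered of the pair at -1.46 ± 0.25. The pair was named because it passed after that scaling, so this outcome was largely fixed in advance. Nor does it cover an effect of less RNA on signals near the floor, such as miR-451a at 10 Gy. A different content of red cells or their RNA in the sera, as from hemolysis during collection, may be a candidate explanation. The other red-cell-rich miRNAs tested had a median change of -1.46 (miR-25-3p -1.63 ± 0.36, miR-92a-3p -1.29 ± 0.58), but only 2 of 10 could be tested and 0 passed, so it cannot be told apart from a dose effect on red cells. In intestine, where miR-486a-5p rose (0.29 for its only detected probe), miR-451a had a change of 0.21 ± 0.26.

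The miR-466, miR-467 and miR-669 family had 58 members on the array, of which 11 were tested in feces, 11 had a positive change (0.97 to 2.48) and 8 passed, with a median of 2.11 (2.16 and 1.97 within slide rows 1 and 2). The choice of scaling did not remove the rise of the median, which after quantile normalization was 1.96 (1.48 to 2.10) against 0.19 for all tested miRNAs. That interval resamples the members, which are not independent, and leaves out the spread between arrays. Whether members passed did depend on the processing. None passed (0 members) without scaling (median 1.27, all tested -0.49), with normexp (0.68), without 0 Gy replicate 1 (1.81) or without 10 Gy replicate 1, 2, 3 or 4 (2.09, 2.19, 2.19, 1.73). The members' deviations from the group means correlated at 0.823 on average, against a 95th percentile of 0.199 in 1000 random lists, which is consistent with probes that read near-identical members or 1 common RNA, so the 8 calls may amount to far fewer independent changes. Transcription of the gene cluster within Sfmbt2, which holds 66 of 75 family genes, could not be decided, since 5 members with genes inside it exceeded 5 with genes elsewhere by 0.28 (-0.42 to 1.18). In serum 2 members were tested (median -0.05, 0 passed) and in intestine 9 (median 0.16, 1 passed).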
